A study of Arabidopsis thaliana with 12 samples.

How the data were processed

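The data are RNA-seq profiles of total RNA from Arabidopsis seedlings sequenced on a DNBSEQ-T7, per the labels. Seeds were kept at 4 °C for 2 days and seedlings grew at 22 °C in continuous light for 6 days before the dark treatment, per the labels. The authors deposited 1 table per line. The submitters' processing notes name kallisto 0.46.2, which estimates transcript abundance without alignment, sleuth 0.30.0, a testing tool for it, and the build TAIR10. The notes give neither the role nor the order of these tools. Each deposited table holds TPM values for 6 libraries, a fold ratio and a p-value per gene. That the values are TPM is read from the file headers and the totals, 929954 to 935223 in each library. The deposited tables list 1 transcript per gene for 27655 genes. Other transcripts of a gene are not used here, so a switch between transcripts can appear as a change in level. For 971 genes the tables of the 2 lines list different transcripts. These genes were left out of every comparison across lines, which leaves 26684. TPM values carry no read number, so no counting error or depth can be given. Gene symbols come from the gene lists written for this work and from the RefSeq annotation of TAIR10.1, which held 27445 of the gene identifiers. As that build is not named in the notes, no coordinates are given.

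Groups were taken from the library descriptions. The genotype field names flu1-1 for all libraries and conflicts with the titles and the series design for the flu1-5 ex1 samples. The labels give 1 value of the batch field for all samples, so no batch can be compared.

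Values were transformed as log2(TPM + 1), and genes with a mean of at least 1 TPM over the libraries fitted were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes moderation (statmod 1.5.0). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes within a line. A difference between lines can be overstated or understated on that scale, where low levels differ between the lines. The Benjamini-Hochberg method adjusted p-values over the genes tested, with a threshold of 0.05. Light was compared with dark in the 6 libraries of each line alone. The difference between lines was an interaction term over all 12 libraries, and the lines were compared directly within dark and within light. All p-values from limma are two-sided. An exact 0 can be a failed estimate, so genes at 0 in every library of a group are given as listed values with no fold. For genes that share sequence with close copies, such as the LHCB1 genes, HSP17.6 genes, BIP1 and BIP2, or LSU genes, the estimate may be split between copies.

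Gene lists were fixed before the data were examined, as were the main tests, the alternatives and the rule for named genes. The 19 lists cover early singlet oxygen response, hydrogen peroxide and antioxidant enzymes, detoxification, unfolded protein response, jasmonate, salicylic acid and immunity, ethylene and ERF factors, WRKY factors, calcium and touch, heat shock, mitochondrial dysfunction, light-induced protection and flavonoids, dark and sugar starvation, PIF and shade, circadian clock, nuclear photosynthesis, chloroplast-encoded genes, tetrapyrrole synthesis, and root and root hair markers. Some genes stand in more than 1 list. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation. The rule names, for each line, the 10 largest rises and the 10 largest falls among called genes with a mean level at or above the median of the genes tested. It names the 10 largest differences in each direction by the same rule, and for each list the 2 called members with the largest rise and the 2 with the largest fall in each line. FLU, EX1, EX2, AAA-ATPase, BAP1, ZAT12, ELIP1, ELIP2, SEN1, HSP21, LOX3 and FER1 were named whatever their result. ZAT10, WRKY40 and FLS1 were named outside the rule, after their values were seen. Overlap was tested by Fisher's exact test.

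Alternatives were quantile normalization, no filter beyond genes at 0 in every library, a mean of at least 5 TPM, pseudocounts of 0.1 and 5, the replicate number as a block, leaving out each library, an adjusted p under 0.01, a change of at least 2-fold, the deposited p-value, and for lists an estimated correlation and ranks. Reading the deposited effect on another log scale was planned and not needed, because the deposited fold is linear. Of the alternatives, those for the lines within dark and within light and the list tests without each library were chosen after seeing the data.

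The procedure was tested on simulated libraries with the real levels and spread and 200 changed genes, far fewer than were called in the data. Noise was drawn for each gene on its own, so the simulated genes did not vary together. For light in flu1-1 ex1 (18060 genes tested) it recovered 22.4% of genes changed 1.2-fold, 86.6% of those changed 1.5-fold and 98.5% of those changed 2-fold. For light in flu1-5 ex1 (18091 genes) it recovered 31.3%, 76.1% and 97.0%, and for the difference (17762 genes) 26.9%, 64.2% and 89.4%. Unchanged genes made up 1.81%, 7.56% and 5.30% of the calls. A list shifted by 1 on the log2 scale was called in each simulation. Of the other 18 lists, camera called 1 in the simulation of light in flu1-1 ex1 and 0 in that of light in flu1-5 ex1 and that of the difference. These list counts cannot tell how camera at the preset correlation behaves where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.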

Results

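Transcript levels were measured by RNA-seq in Arabidopsis thaliana seedlings of 2 lines, flu1-1 ex1 and flu1-5 ex1. FLU is a chloroplast protein that represses chlorophyll synthesis in the dark. Without it, a chlorophyll precursor builds up in darkness and releases singlet oxygen, a reactive form of oxygen, when light returns. The 2 lines carry different alleles of flu, and both also carry ex1, a mutation in EXECUTER1, a chloroplast protein needed for much of the known response to singlet oxygen. Seedlings 6 days old were sampled after 4 h of darkness, or after 4 h of darkness and 1 h of light. Each of the 4 groups had 3 libraries. No group was without a flu or an ex1 mutation, and none was kept dark for the further 1 h. For a change in light, responses to singlet oxygen, to light itself and to elapsed time therefore cannot be told apart. Per the file headers, about 100 seedlings went into each replicate. Nothing in the labels says that replicates were grown apart, so the p-values measure the spread between these samples, which may be technical. Each library held a level in TPM, a relative abundance corrected for transcript length, for 27655 genes, and 17660 to 18169 of them reached 1 TPM. TPM keeps no trace of the number of reads, so the depth of each library is unknown. Within groups, pairs of libraries correlated across genes at Pearson r of 0.9935 to 0.9947. The first principal component held 79.3% of the variance and the second 11.8%.

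The mutated genes were examined first. FLU (AT3G14110) stood at 190.3 ± 6.33 TPM in dark and 191 ± 1.65 TPM in light in flu1-1 ex1 (SD, n = 3). In flu1-5 ex1 it stood at 14.2 ± 1.21 TPM and 15.5 ± 1.46 TPM (SD, n = 3). The difference between lines was -3.66 on the log2 scale in dark (SE 0.057, limma adjusted p = 5.82e-09). Light did not change FLU detectably in either line (adjusted p = 0.895 and 0.245). The genotype field of the labels gives flu1-1 for all 12 libraries, whereas the titles, descriptions and series design separate the lines. The grouping used here follows the descriptions. The 6 libraries so assigned to flu1-1 ex1 had 184.3 to 196.9 TPM of FLU and the other 6 had 13.2 to 17 TPM. EXECUTER1 (EX1, AT4G33630) transcript was present in both lines. It rose in light from 40.1 ± 2.64 to 51 ± 1.81 TPM in flu1-1 ex1 and from 45.3 ± 0.47 to 81 ± 6.66 TPM in flu1-5 ex1 (adjusted p = 0.000402 and 2.25e-06). EXECUTER2 (EX2, AT1G27510), its relative, fell from 69.3 ± 2.75 to 57 ± 1.91 TPM and from 71.5 ± 1.33 to 58.2 ± 1.32 TPM. A transcript level does not tell whether the mutated protein is made.

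Levels are given from here on as the mean ± SD of 3 libraries. The first comparison asked which transcripts changed in flu1-1 ex1 within 1 h of light after dark. Several heat shock genes were among the 10 largest rises given by the rule for named genes. The chaperone gene HSP70-4 (AT3G12580) rose from 6.5 ± 0.198 to 949.8 ± 4.59 TPM, a log2 change of 6.99 (SE 0.031). HSP90.1 (AT5G52640) rose from 6.96 ± 0.864 to 613 ± 15.1 TPM and the small heat shock gene HSP17.8 (AT1G07400) from 3.25 ± 0.183 to 307 ± 12 TPM. Among the 10 largest falls by that rule were SEN5, DYL1, MIOX2 and ERD5, of which SEN5 alone belongs to the list of dark and sugar starvation genes. SEN5 (AT3G15450) fell from 2435 ± 55.4 to 75.2 ± 4.38 TPM, and DYL1 (AT1G28330), a dormancy-associated gene, from 541 ± 80.9 to 26.1 ± 7.5 TPM. MIOX2 (AT2G19800), a myo-inositol oxygenase, fell from 511 ± 4.6 to 17.3 ± 0.875 TPM, and ERD5 (AT3G30775), a proline dehydrogenase, from 678 ± 15.8 to 37.8 ± 1.65 TPM. Large rises were also found for 2 genes of sulphur metabolism. LSU2 (AT5G24660) rose from 2.42 ± 0.237 to 164 ± 7.85 TPM and APR1 (AT4G04610), which reduces activated sulphate, from 10.5 ± 0.467 to 229 ± 10.3 TPM. Squalene monooxygenase-like SQP1 (AT5G24150) went from 1.2 ± 0.218 to 89.7 ± 0.836 TPM. In all, 13097 of 18042 genes passed the threshold in limma on log2(TPM + 1) (7942 higher and 5155 lower in light), and 2102 rose and 1193 fell at least 2-fold. After quantile normalization the split was 6386 higher and 6751 lower. That scaling moved the median of all genes by 0.14 on the log2 scale, from 0.12 to -0.024, so small changes hold only relative to the other genes.

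Gene lists were tested next, and 10 of the 19 were called in flu1-1 ex1. Counts of members are adjusted over all genes tested. Counts adjusted over the list alone were the same for light in each line, for the difference, and for the lists given within dark and within light, except where a list is given with both. Counts marked as adjusted over all genes only are set apart from this. Of 23 measured heat shock genes, 21 rose and 1 fell, with a median log2 change of 4.2 (camera adjusted p = 6.13e-08). The list for light-induced protection and flavonoids had 15 of 16 measured members higher and 1 lower, with a median of 2.93 (adjusted p = 1.73e-06). ELIP1 (AT3G22840), an early light-induced protein, rose from 0.516 ± 0.156 to 59.9 ± 2.3 TPM and ELIP2 (AT4G14690) from 2.37 ± 0.25 to 131 ± 4.32 TPM. Of 17 genes of dark and sugar starvation, 16 fell and 1 rose, with a median of -3.03 (adjusted p = 3.93e-11). TPS11 (AT2G18700) fell from 73.9 ± 1.04 to 4.08 ± 0.239 TPM, SEN1 (AT4G35770) fell from 1368 ± 39.4 to 817 ± 13.9 TPM, and DIN9 (AT1G67070) rose from 2.04 ± 0.345 to 4.67 ± 1.55 TPM. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0301, 0.0370 and 0.0301). The other 7 called lists did not. All 12 measured genes of the unfolded protein response rose (median 0.96, adjusted p = 0.000217, and adjusted p = 0.0630 with an estimated correlation), among them the chaperone BIP2 (AT5G42020) from 46.5 ± 0.14 to 263 ± 6.7 TPM. Of 27 detoxification genes, 21 rose and 4 fell (adjusted p = 0.00272, and adjusted p = 0.201 with an estimated correlation). The glutathione transferase gene GSTU5 (AT2G29450) rose from 28.6 ± 0.823 to 451 ± 5.1 TPM. Of 6 genes of the mitochondrial dysfunction response 5 rose (adjusted p = 0.0118, and adjusted p = 0.171 with an estimated correlation), including OM66 (AT3G50930) from 1.44 ± 0.152 to 24 ± 1.11 TPM.

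Nuclear photosynthesis genes mostly fell in flu1-1 ex1, with 35 of 42 lower and 4 higher and a median log2 change of -0.42 (camera adjusted p = 1.31e-10, and adjusted p = 0.201 with an estimated correlation). The light-harvesting gene LHCB1.4 (AT2G34430) fell from 2674 ± 73.2 to 668 ± 8.42 TPM, while PSBS (AT1G44575), a photoprotective protein of photosystem II, rose from 1301 ± 25.8 to 1859 ± 16 TPM. Of 23 chloroplast-encoded genes 5 were called lower over all genes and 0 when adjusted over the list alone (adjusted p = 0.00139, and adjusted p = 0.532 with an estimated correlation). The list kept its call without each library, but the number of members called lower was 1 without light replicate 1, 2 without light replicate 2 and 9 without light replicate 3. Dark replicate 3 stood apart, with 2.87% of its TPM from chloroplast genes against 2.06% and 2.01% in the other dark libraries. Of the members named by the rule, rpoA (ATCG00740, log2 change -0.72) lost its call without dark replicate 2 (adjusted p = 0.0804) and without light replicate 1 or 2 (0.114 and 0.0992), and ndhF (ATCG01010, -0.91) without light replicate 1 (0.0552). Ethylene synthesis and ERF factors had 9 of 13 members lower and 3 higher (adjusted p = 0.0181, and adjusted p = 0.201 with an estimated correlation). The PIF and shade list had 8 of 12 lower and 2 higher (adjusted p = 0.0296, and adjusted p = 0.201 with an estimated correlation). With quantile normalization these last 2 lists missed the threshold, at adjusted p = 0.0581 and 0.0559, and the PIF and shade list also missed it without dark replicate 2 (0.0706). Early singlet oxygen response genes were not called as a list in this line (adjusted p = 0.663). Of 15 measured, 9 rose and 4 fell. The zinc finger gene ZAT12 (AT5G59820) rose from 3.44 ± 0.819 to 36.4 ± 1.2 TPM and the kinase gene OXI1 (AT3G25250) from 0.321 ± 0.102 to 10.9 ± 0.683 TPM. ERF6 (AT4G17490) fell from 18.1 ± 1.45 to 9.93 ± 0.458 TPM and the glutaredoxin gene GRXS13 (AT1G03850) from 27.9 ± 0.928 to 2.99 ± 0.276 TPM. BAP1 (AT3G61190), a membrane-associated cell death inhibitor, stood at 1.06 ± 0.302 TPM in dark and 1.67 ± 0.214 TPM in light (adjusted p = 0.0436). That call was lost without dark replicate 1 or 3 (adjusted p = 0.0582 and 0.143), without light replicate 1 or 2 (0.0899 and 0.124), with quantile normalization (0.278) and with a pseudocount of 0.1 (0.0526). AAA-ATPase (AT3G28580) had a mean under 1 TPM over the 6 libraries and was not tested in this line (0.0348 ± 0.0354 and 0.738 ± 0.0213 TPM). HSP21 (AT4G27670) was listed at 0 in the 3 dark libraries and at 0.439, 0.58 and 0.445 TPM in the light libraries. Of 18 genes of hydrogen peroxide and antioxidant enzymes, 5 rose and 11 fell (adjusted p = 0.0761), and the ferritin gene FER1 (AT5G01600) had a log2 change of -1.47 (SE 0.024). Jasmonate genes had 14 of 24 higher and 6 lower, or 15 and 6 adjusted over the list alone (adjusted p = 0.348). Salicylic acid and immunity had 7 of 11 higher and 3 lower (0.638). WRKY factors had 5 of 17 higher and 8 lower, or 6 and 8 adjusted over the list alone (0.170). Calcium and touch had 3 of 8 higher and 4 lower (0.348), and circadian clock 8 of 13 higher and 2 lower (0.149). Tetrapyrrole synthesis had 10 of 29 higher and 16 lower, or 11 and 16 adjusted over the list alone (0.149), with a median of -0.11, a mean of 0.023 and a test direction of lower.

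The same question was asked of flu1-5 ex1. Heat shock genes were again among the largest rises. HSP70-4 rose from 4.82 ± 0.314 to 1269.9 ± 7.25 TPM (log2 change 7.77, SE 0.042). HSP17.6A (AT5G12030) rose from 0.254 ± 0.226 to 232 ± 1.64 TPM and HSP17.4 (AT3G46230) from 0.535 ± 0.111 to 157 ± 4.82 TPM. The heat shock factor gene HSFA2 (AT2G26150) was listed at 0 in the 3 dark libraries and at 92.4, 91.4 and 84.4 TPM in the light libraries. HSP21 was likewise listed at 0 in dark and at 6.77, 7.48 and 5.51 TPM in light. ZAT12 rose from 16.1 ± 1.31 to 261 ± 6.66 TPM, OXI1 from 1.28 ± 0.192 to 36.1 ± 0.888 TPM, BAP1 from 3.13 ± 0.691 to 15.3 ± 1.33 TPM and AAA-ATPase from 0.204 ± 0.0674 to 2.83 ± 0.274 TPM. WRKY46 (AT2G46400), a stress-related transcription factor, rose from 1.24 ± 0.129 to 99.9 ± 2.58 TPM. CML37 (AT5G42380), a calmodulin-like protein, rose from 0.156 ± 0.0545 to 61.9 ± 4.58 TPM. Among the largest falls were BT2 (AT3G48360), from 228 ± 8.86 to 10.8 ± 1.27 TPM, the phosphate-induced gene PHI-1 (AT1G35140), from 128 ± 2.48 to 6.72 ± 0.955 TPM, and SEN5, from 1845 ± 22.7 to 134 ± 3.44 TPM. In limma 12297 of 18145 genes passed the threshold (6973 higher and 5324 lower in light), and 1811 rose and 921 fell at least 2-fold. After quantile normalization the split was 5649 higher and 7016 lower, with the median of all genes moved by 0.12.

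By gene list, 14 of the 19 lists were called in flu1-5 ex1, and with an estimated correlation none kept its call. Of 18 early singlet oxygen response genes 16 rose and 2 fell, with a median log2 change of 1.89 (camera adjusted p = 3.92e-06, and adjusted p = 0.0599 with an estimated correlation). The 2 that fell were GRXS13, from 26.2 ± 2.37 to 3.77 ± 1.35 TPM, and ERF1A (AT4G17500), from 82.1 ± 5.05 to 68.1 ± 0.335 TPM. Heat shock genes rose in 24 of 25 cases, with a median of 5.57 (adjusted p = 2.09e-13, and adjusted p = 0.0774 with an estimated correlation). The remaining member, HSFA3 (AT5G03720), was at 14 ± 0.582 and 14 ± 0.128 TPM. Calcium and touch genes rose in 8 of 9 cases and fell in 1 (adjusted p = 0.00367, and adjusted p = 0.0874 with an estimated correlation). RBOHD (AT5G47910), an oxidase that makes superoxide at the cell surface, rose from 18.8 ± 0.495 to 102 ± 5.05 TPM. Detoxification genes rose in 24 of 27 cases and fell in 2 (adjusted p = 9.16e-08, and adjusted p = 0.0746 with an estimated correlation). CYP81D8 (AT4G37370), a cytochrome P450, fell from 82.7 ± 3.03 to 48.2 ± 1.93 TPM. Jasmonate genes rose in 14 of 24 cases and fell in 6 (adjusted p = 0.0488, and adjusted p = 0.154 with an estimated correlation). The list lost its call without dark replicate 1 or light replicate 3 (0.0688 and 0.0849) and with the replicate block. LOX3 (AT1G17420) and AOC3 (AT3G25780), enzymes of jasmonate synthesis, rose from 3.53 ± 0.191 to 45 ± 2.59 TPM and from 1.39 ± 0.19 to 45.3 ± 3.05 TPM. Salicylic acid and immunity genes rose in 7 of 11 cases and fell in 2 (adjusted p = 0.0453, and adjusted p = 0.247 with an estimated correlation). SARD1 (AT1G73805), an activator of salicylic acid synthesis, rose from 1.62 ± 0.127 to 13.8 ± 0.677 TPM. Unfolded protein response genes rose in 10 of 12 cases (adjusted p = 7.75e-05, and adjusted p = 0.130 with an estimated correlation). All 6 genes of the mitochondrial dysfunction response rose (adjusted p = 0.00135, and adjusted p = 0.0788 with an estimated correlation). Circadian clock genes rose in 10 of 13 cases and fell in 1 (adjusted p = 0.00796, and adjusted p = 0.172 with an estimated correlation). GI (AT1G22770) rose from 3.28 ± 0.173 to 43.1 ± 0.922 TPM.

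Light-induced protection genes rose in 15 of 16 cases and fell in 1 in flu1-5 ex1 (median 2.26, adjusted p = 1.82e-07, and adjusted p = 0.0599 with an estimated correlation). ELIP1 reached 40.5 ± 1.55 TPM and ELIP2 116 ± 6.58 TPM. Dark and sugar starvation genes fell in 16 of 17 cases and rose in 1 (median -2.32, adjusted p = 4.66e-10, and adjusted p = 0.0746 with an estimated correlation). Nuclear photosynthesis genes fell in 32 of 42 cases and rose in 5 (median -0.26, adjusted p = 2.21e-06, and adjusted p = 0.172 with an estimated correlation). LHCB1.4 fell from 1403 ± 13.4 to 591 ± 34.2 TPM and LHCB2.1 (AT2G05100) rose from 134 ± 7.56 to 242 ± 9.69 TPM. Tetrapyrrole synthesis genes, which make chlorophyll and heme, fell in 19 of 29 cases and rose in 7 (adjusted p = 0.0162, and adjusted p = 0.154 with an estimated correlation). GUN4 (AT3G59400) rose from 47.2 ± 3.39 to 216 ± 31 TPM and PORB (AT4G27440) fell from 308 ± 17.5 to 161 ± 4.62 TPM. With quantile normalization the photosynthesis and tetrapyrrole lists missed the threshold (adjusted p = 0.0561 and 0.0547). Chloroplast-encoded genes were lower in 14 of 23 cases, or 12 adjusted over the list alone (adjusted p = 0.000912, and adjusted p = 0.526 with an estimated correlation). The list kept its call without each library, but the number of members called lower was 7, 4 and 4 without dark replicate 1, 2 or 3, and 22, 9 and 4 without light replicate 1, 2 or 3. Light replicate 1 stood apart, with 1.82% of its TPM from chloroplast genes against 1.21% and 1.38% in the other light libraries and 1.85% to 2.15% in the dark libraries. Of the members named by the rule, ndhA (ATCG01100, log2 change -0.75) lost its call without any 1 of the dark replicates or light replicate 3 (adjusted p from 0.0637 to 0.119) and with the replicate block (0.0778). The other, rpoA (-0.73), lost it without any 1 of the dark replicates or light replicate 2 or 3 (0.0674 to 0.130) and with the replicate block (0.0888). It also lost it with a mean of at least 5 TPM (0.0539) and with a pseudocount of 0.1 or 5 (0.0525 and 0.05004). The lists not called were hydrogen peroxide and antioxidant enzymes (5 of 18 higher and 9 lower, adjusted p = 0.229), ethylene and ERF factors (7 of 15 higher and 5 lower, 0.561), WRKY factors (9 of 18 higher and 6 lower, 0.308) and PIF and shade (5 of 11 higher and 4 lower, 0.608). The hydrogen peroxide list had a median of -0.14, a mean of 0.012 and a test direction of lower.

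**Figure D1:**
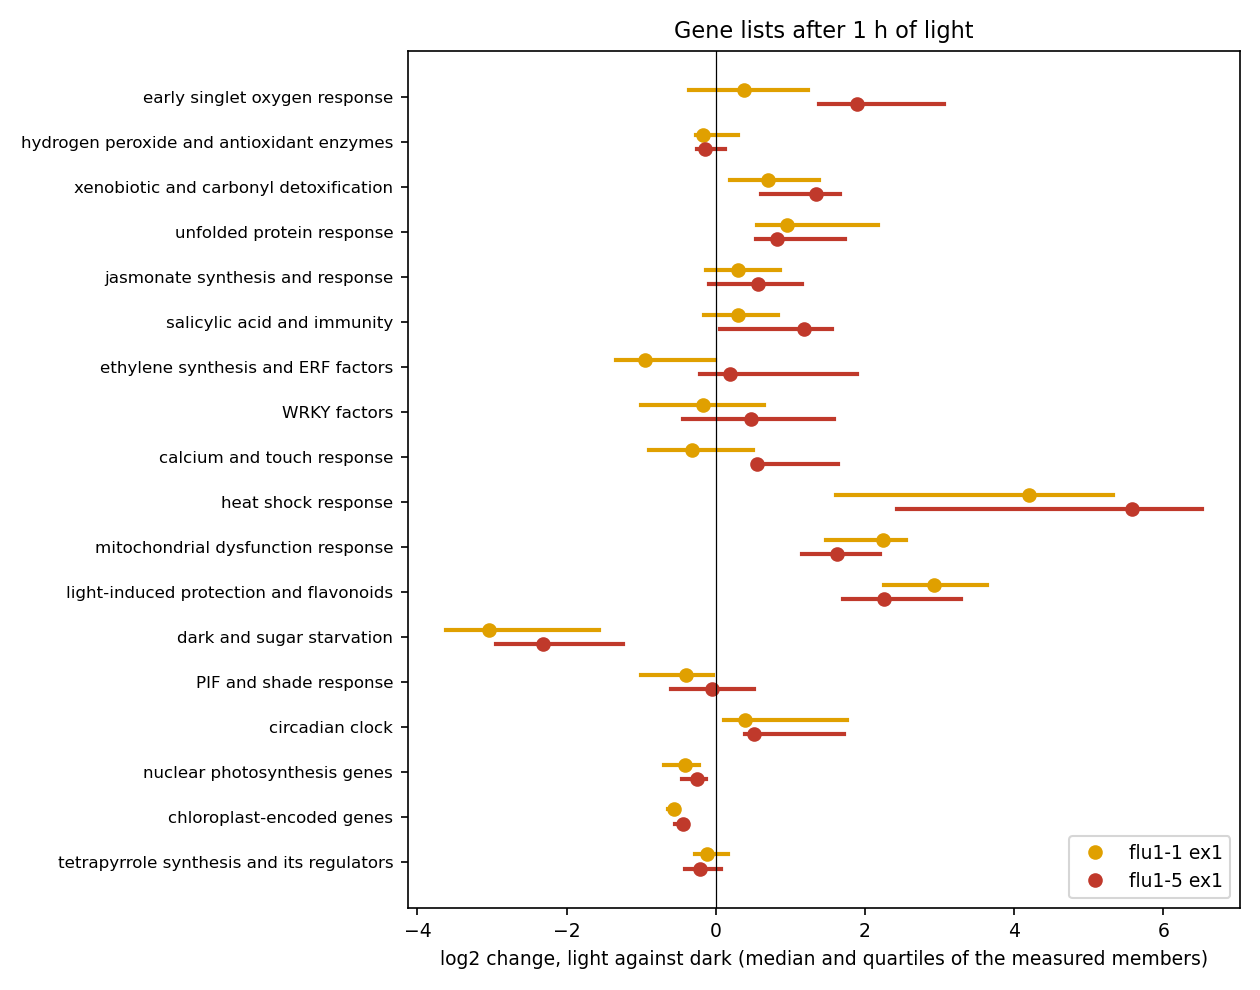
Median (points) and quartiles (bars) of the log2 change in light against dark over the measured members of 18 gene lists, in flu1-1 ex1 and flu1-5 ex1. The early singlet oxygen list had a median of 0.38 in flu1-1 ex1 and 1.89 in flu1-5 ex1, and the dark and sugar starvation list -3.03 and -2.32. Members were filtered by level within each line, so the early singlet oxygen median covers fewer genes in flu1-1 ex1.

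The third comparison tested the difference itself, the light response of flu1-5 ex1 less that of flu1-1 ex1. Among the largest differences by the rule for named genes, MYB15, CML37 and HSP17.6C were higher in flu1-5 ex1, and APR1, SHM7 and LSU3 were lower. MYB15 (AT3G23250), a defence-related transcription factor, went from 0.163 ± 0.11 to 2.75 ± 0.449 TPM in flu1-1 ex1 and from 0.345 ± 0.298 to 61.6 ± 3.27 TPM in flu1-5 ex1, a difference of 3.88 on the log2 scale (SE 0.22, adjusted p = 3.35e-08). CML37 went from 0.0472 ± 0.0464 to 3.58 ± 0.276 TPM in flu1-1 ex1, and its difference was 3.64 (SE 0.13, adjusted p = 5.91e-10). HSP17.6C (AT1G53540) rose from 0.405 ± 0.235 to 15.3 ± 2.11 TPM and from 0.191 ± 0.191 to 107 ± 5.9 TPM. ERF6, which fell in flu1-1 ex1, rose in flu1-5 ex1 from 26.1 ± 2.26 to 105 ± 3.81 TPM (difference 2.78, SE 0.095). CML38 (AT1G76650) likewise fell from 10.8 ± 2.28 to 3.59 ± 0.334 TPM and rose from 26.2 ± 3.57 to 61.1 ± 7.02 TPM. BAP1 had a difference of 1.61 (SE 0.20, adjusted p = 5.37e-05), ZAT12 of 0.84 (SE 0.14), LOX3 of 1.73 (SE 0.089) and FER1, which fell less in flu1-5 ex1, of 1.02 (SE 0.032). In the other direction, APR1 rose from 19 ± 0.598 to 71.1 ± 3.97 TPM in flu1-5 ex1, for a difference of -2.48 (SE 0.070, adjusted p = 1.09e-10). SHM7 (AT1G36370), a hydroxymethyltransferase, rose from 20.9 ± 0.729 to 95.4 ± 2.43 TPM in flu1-1 ex1 and fell from 39.7 ± 1.12 to 32.8 ± 0.791 TPM in flu1-5 ex1. LSU3 (AT3G49570) went from 1.3 ± 0.258 to 47.3 ± 1.05 TPM and from 3.21 ± 0.447 to 17.78 ± 1.81 TPM. OXS3 (AT5G56550), a stress tolerance gene, went from 53.7 ± 3.04 to 41.9 ± 1.22 TPM and from 46 ± 2.88 to 6.32 ± 0.812 TPM. In all, 5273 of 17830 genes passed the threshold (2012 with a higher and 3261 with a lower difference), and 362 and 142 of them differed at least 2-fold. At an adjusted p under 0.01, 3308 genes passed.

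**Figure D2:**
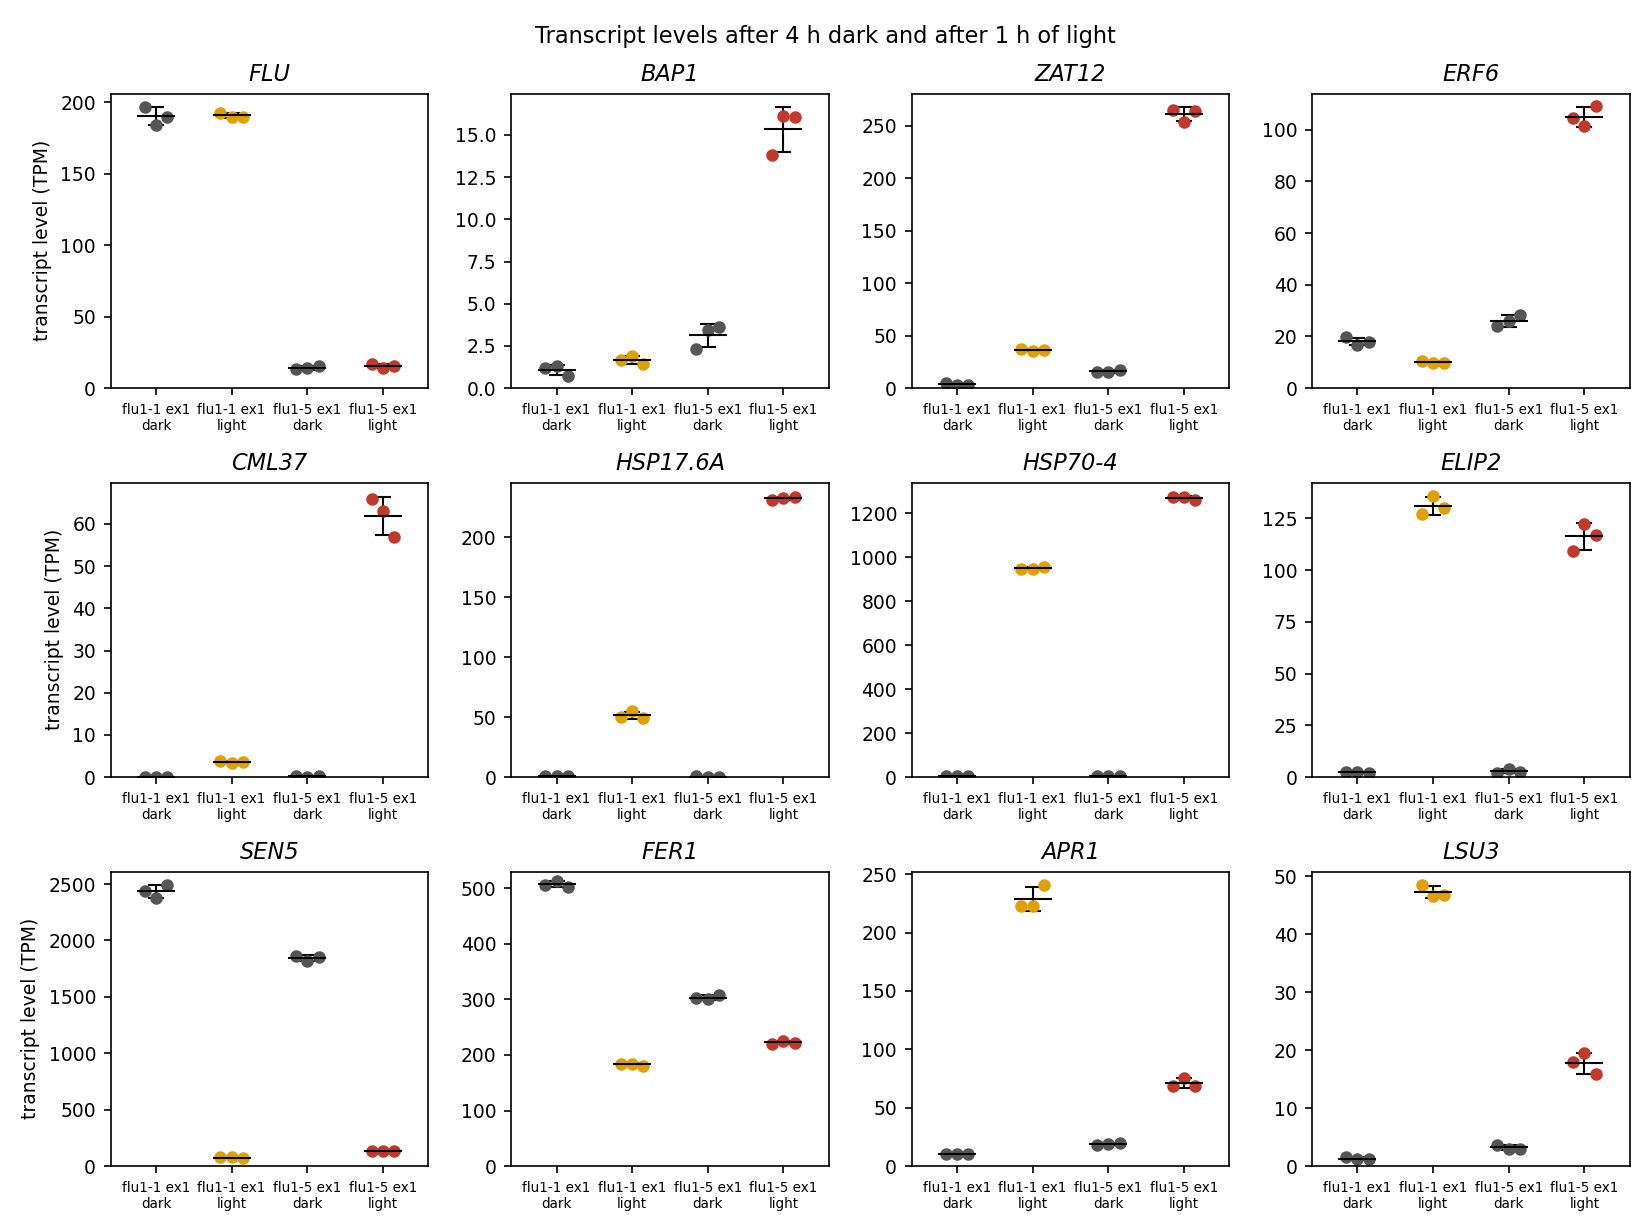
Transcript level in TPM on linear axes for 12 genes, one panel each, in the 3 libraries of each group (points) with the mean and SD (bars). BAP1 reached 15.3 TPM in light in flu1-5 ex1 and 1.67 TPM in flu1-1 ex1, while LSU3 reached 17.78 and 47.3 TPM.

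For genes at or near 0 in a group, the values of the libraries were as follows. ERF105 (AT5G51190) was listed at 0 in all 6 flu1-1 ex1 libraries. In flu1-5 ex1 it had 8.75, 2.35 and 10.2 TPM in dark and 118.6, 117.7 and 117.6 TPM in light, so no fold is given. MYC2 (AT1G32640), a jasmonate regulator, had 0, 0.0182 and 0 TPM in the flu1-1 ex1 dark libraries against 5.2 ± 1.73 TPM in flu1-5 ex1. In light it had 20.7 ± 1.73 and 40.1 ± 2.07 TPM, so it was higher in flu1-5 ex1 in both conditions. Its difference of -1.66 rests on the dark level near 0, and was -0.20 and not called with a pseudocount of 5 (adjusted p = 0.292, with 5.52e-08 to 0.292 over all alternatives). AT1G47130 had 1.54, 0 and 0 TPM in dark and 12, 25.3 and 9.55 TPM in flu1-1 ex1 in light and 233 ± 7.55 TPM in flu1-5 ex1, and its difference of 3.03 was 1.32 and not called with a pseudocount of 0.1 (adjusted p = 0.507, with 4.04e-05 to 0.507 over all alternatives). ELIP1 had a difference of -0.51 (adjusted p = 0.00745), which was lost with a pseudocount of 0.1 (adjusted p = 0.216, with 4.77e-05 to 0.216 over all alternatives). ELIP2 was not called (adjusted p = 0.195), except without flu1-5 ex1 dark replicate 1 (-0.52, adjusted p = 0.0232, with 0.0232 to 0.340 over all alternatives).

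For the difference, 13 of the 19 lists were called. Early singlet oxygen response genes had 16 of 17 measured members higher in the difference and 0 lower, with a median of 1.23 (camera adjusted p = 1.34e-18). The remaining member, GRXS13, had adjusted p = 0.34. Heat shock genes had 23 of 25 higher, or 24 adjusted over the list alone, with a median of 1.03 (adjusted p = 2.89e-24). Calcium and touch genes had 8 of 9 higher (median 1.36, adjusted p = 4.87e-13), among them TCH4 (AT5G57560), which fell from 164 ± 2.92 to 24.5 ± 2.09 TPM in flu1-1 ex1 and from 292 ± 4.63 to 249 ± 6.06 TPM in flu1-5 ex1. WRKY factors had 11 of 18 higher and 1 lower, or 13 and 1 adjusted over the list alone (median 0.65, adjusted p = 3.72e-10). Ethylene and ERF factors had 11 of 16 higher and 3 lower (median 0.89, adjusted p = 3.44e-07). Salicylic acid and immunity had 6 of 11 higher (median 0.32, adjusted p = 1.02e-05), and detoxification had 17 of 27 higher and 6 lower, or 18 and 7 adjusted over the list alone (median 0.40, adjusted p = 2.36e-06). Jasmonate genes had 9 of 24 higher and 4 lower (median 0.051, adjusted p = 0.00695). Dark and sugar starvation genes, which fell in both lines, had a higher difference in 14 of 16 cases and a lower one in 1 (median 0.67, adjusted p = 5.61e-14), so that their fall was smaller in flu1-5 ex1. They were already lower there in dark, in 10 of 16 cases or 11 adjusted over the list alone (median -0.22, adjusted p = 1.04e-11, and adjusted p = 0.0593 with an estimated correlation), so part of the smaller fall is a lower starting level. In light they were higher in 13 of 15 cases and lower in 1 (median 0.51, adjusted p = 1.13e-05). A smaller fall in flu1-5 ex1 was not confined to this list, being called for 810 of the 4097 genes that fell in both lines. Light-induced protection genes had 8 of 16 lower and 1 higher (median -0.38, adjusted p = 0.00668). FLS1 (AT5G08640), a flavonol synthase, differed by -1.44 on the log2 scale (adjusted p = 0.00963). The PIF and shade list had 5 of 12 higher and 2 lower (adjusted p = 0.0161). In dark, 5 of its members were lower in flu1-5 ex1 and 0 higher, and in light 3 and 3 (adjusted over all genes only). As a list it was not called in light (camera adjusted p = 0.861), so its difference lies mainly in a lower starting level. These 11 lists kept their calls with an estimated correlation (adjusted p from 0.000193 to 0.0462). Nuclear photosynthesis genes had 23 of 41 higher and 2 lower, or 27 and 2 adjusted over the list alone (median 0.19, adjusted p = 4.33e-11, and adjusted p = 0.0529 with an estimated correlation). They were mostly lower in flu1-5 ex1 in dark, as given below. In light 20 of them were still lower there and 6 higher (adjusted over all genes only). For the list as a whole the higher difference therefore lies in a lower starting level, not in a higher level in light. Clock genes had 4 of 11 higher and 1 lower, or 6 and 2 adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.0708 with an estimated correlation). Not called were hydrogen peroxide and antioxidant enzymes (6 of 18 higher and 5 lower, adjusted p = 0.199), the unfolded protein response (2 of 12 higher and 5 lower, 0.0977) and chloroplast-encoded genes (0 of 23 called, 0.199). The chloroplast list was called higher without flu1-1 ex1 dark replicate 2 (0.0473), flu1-1 ex1 light replicate 3 (0.0295) or flu1-5 ex1 light replicate 2 (0.0215). Also not called were the mitochondrial dysfunction response (1 of 6 higher and 1 lower, or 1 and 2 adjusted over the list alone, adjusted p = 0.391) and tetrapyrrole synthesis (5 of 29 higher and 10 lower, or 5 and 11 adjusted over the list alone, 0.180). Of the 8 root and root hair markers only 1, PIP2-4 (AT5G60660), reached the level needed for a test, with 1.48 to 2.57 TPM over the 12 libraries, and it was not called in either line or in the difference (adjusted p of the list = 0.803, 0.608 and 0.869).

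The overlap of the responses was counted over 17529 genes tested in both lines, which share no libraries. Genes that rose in both lines numbered 5993, against 2997 for independent lists, and those that fell in both numbered 4097, against 1507 (one-sided Fisher's exact test, p at or below 1e-300 each, the lowest value written). HSP70-4, ELIP2 and GSTU5 are among the former and SEN5 and LHCB1.4 among the latter. Opposite calls were made for 326 genes. Of these, 148 rose in flu1-5 ex1 and fell in flu1-1 ex1, such as ERF6, ANAC102 (AT5G63790) and CML38, and 178 went the other way, such as SHM7 and MLP423 (AT1G24020). At a change of at least 2-fold, 1372 rose in both lines and 772 fell in both, and 2 had opposite calls. Across genes the log2 changes had a Pearson r of 0.905 and a Spearman rho of 0.874, with genes not being independent replicates. Of the genes that rose in both lines, 1723 rose less in flu1-5 ex1 and 500 rose more by the test of the difference. Of those that fell in both, 810 fell less in flu1-5 ex1 and 280 fell more. The median log2 change was 0.73 in flu1-1 ex1 and 0.60 in flu1-5 ex1 for the former. For the latter it was -0.63 and -0.55. Among genes called in the same direction in both lines, a smaller response in flu1-5 ex1 was thus the more frequent.

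**Figure D3:**
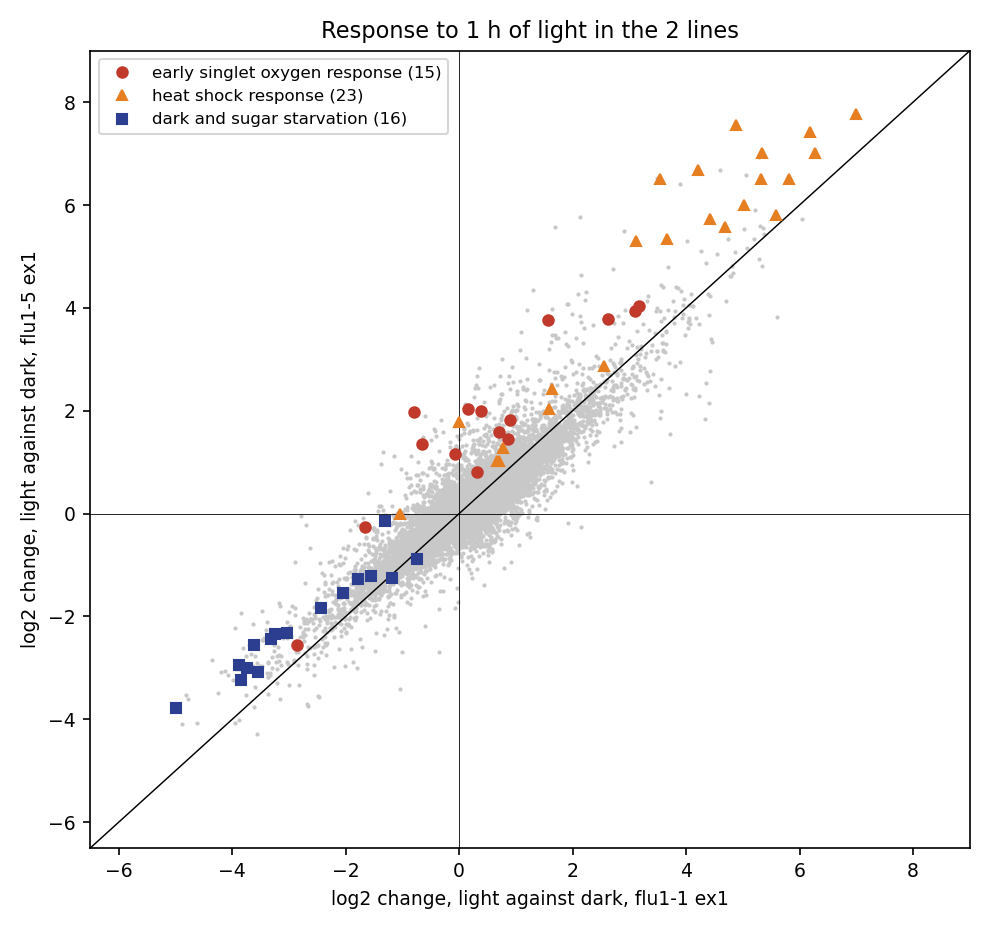
Log2 change in light against dark on the log2(TPM + 1) scale, flu1-1 ex1 on the horizontal and flu1-5 ex1 on the vertical axis. Each grey point is a gene tested in both lines and for the difference, the line marks equal change, and coloured symbols mark 3 lists, such as the early singlet oxygen list with ERF6 at -0.80 and 1.97.

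The lines were also compared directly within each condition. In dark, ZAT12, ZAT10 and WRKY40 were higher in flu1-5 ex1 than in flu1-1 ex1. ZAT12 was at 16.1 against 3.44 TPM (log2 difference 1.96, SE 0.13), ZAT10 (AT1G27730) at 51 against 10.4 TPM and WRKY40 (AT1G80840) at 46.6 against 14.3 TPM. The light-harvesting gene LHCB1.1 (AT1G29920) was lower in dark, at 808 against 2138 TPM. In dark 3233 of 17471 genes differed (2246 higher and 987 lower in flu1-5 ex1), with 161 and 27 at least 2-fold apart. Without flu1-1 ex1 dark replicate 1 the genes lower in dark numbered 636 and those higher 1671. After quantile normalization the split in dark was 1594 higher and 1435 lower. At an adjusted p under 0.01 the count in dark was 1643. Early singlet oxygen genes were higher in 10 of 14 cases in dark, or 11 adjusted over the list alone (median 0.53, adjusted p = 3.85e-08), and calcium and touch genes in 8 of 8 (median 0.78, adjusted p = 1.42e-10). Nuclear photosynthesis genes were lower in 29 of 41 cases and higher in 5, or 7 adjusted over the list alone (median -0.24, adjusted p = 7.95e-20, and adjusted p = 0.0593 with an estimated correlation). In light 6624 of 17845 genes differed (3061 higher and 3563 lower), with 560 and 108 at least 2-fold apart, and 4380 passed at an adjusted p under 0.01. In light, early singlet oxygen genes were higher in flu1-5 ex1 in 17 of 18 cases (median 2.33, adjusted p = 8.65e-20), heat shock genes in 24 of 25 (median 0.99, adjusted p = 3.55e-22) and WRKY factors in 15 of 17 (median 1.43, adjusted p = 7.09e-14). WRKY40 was at 194 against 16.1 TPM and ZAT12 at 261 against 36.4 TPM. Each line is represented by a single stock, so a difference between lines is not separable from other differences between the stocks. As replicates may not have been grown apart, it is not separable from a difference between separately grown samples either.

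The authors' deposited table for each line also gives a fold change and a p-value per gene. The fold in the authors' deposited table equals the ratio of the mean TPM in light to that in dark, to a relative difference of at most 7.22e-15. A p-value under 0.05 stands in the authors' deposited table for 16371 of the 19995 genes with one in flu1-1 ex1, and for 16137 of 20100 in flu1-5 ex1. With at least 2-fold change added, the authors' deposited table holds 2599 higher and 1461 lower genes in flu1-1 ex1 and 2246 higher and 1157 lower genes in flu1-5 ex1. The counts from limma given above use neither column.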

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

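The union of 5 stress lists, the test of library scaling on them, the splits of the libraries by their median, the comparison of splits that mix the lines with others and the limit of 2-fold for the genes given here were chosen after the results were seen. What follows was singled out because the light response differed between the lines by the test of the difference itself. That test called 5273 genes. Of 100 splits of the libraries that exchange lines within dark and within light, 2 called as many, the real one included, and the highest other called 6216. This does not exclude chance for that count, although a share under 0.05 was set as the bound, because the count followed the mixing of the lines. The 90 splits that mix the light libraries of the lines, and so put the difference between lines into the spread, called at most 221 genes, and 80 of them called 0. The 9 others that keep those of a line together called 2801 to 6216. The highest exchanges all light libraries between the lines, so it adds up the 2 differences between lines. Nor can such splits cover chance between separately grown samples, since nothing says that the replicates were grown apart. The test of the difference called 13 lists, and their median differences on the log2 scale were 1.23 for early singlet oxygen response, 1.36 for calcium and touch, 1.03 for heat shock, 0.89 for ethylene and ERF factors, 0.65 for WRKY factors, 0.67 for dark and sugar starvation, 0.40 for detoxification, 0.32 for salicylic acid and immunity, 0.31 for PIF and shade, 0.22 for the circadian clock, 0.19 for nuclear photosynthesis, 0.051 for jasmonate and -0.38 for light-induced protection. With an estimated correlation the nuclear photosynthesis and circadian clock lists lost their calls (adjusted p = 0.0529 and 0.0708). For nuclear photosynthesis and for PIF and shade the difference lay mainly in lower levels in dark, as given above. Of 125 named genes tested, 95 were called, 65 higher and 30 lower. Those at least 2-fold apart are given here, without 3 genes that were at 0 in every library of a group (ERF105, HSP21 and AT1G71000).

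Regulators, signalling genes and genes of the calcium and touch list with a higher difference in flu1-5 ex1 were MYB15 (3.88), CML37 (3.64), ERF6 (2.78), ERF13 (2.76), WRKY46 (2.58), CML38 (2.54), TCH4 (2.47), SARD1 (2.19), ANAC102 (2.02), WRKY15 (1.61), BAP1 (1.61), ERF1A (1.39) and RBOHD (1.36). Heat shock genes were HSP17.6C (2.97), HSP17.6A (2.68), HSP17.4 (2.48), HSP17.6II (1.68), HSP17.8 (1.23) and HSFA3 (1.03). Metabolic genes were AOC3 (2.18), LOX3 (1.73), MIOX2 (1.29), HEMA2 (1.23), ERD5 (1.06), GSTU25 (1.03), FER1 (1.02) and XTR7 (1.01). The others were AT5G54165 (2.53), DIP2 (2.1), AT1G59860 (1.66), DYL1 (1.5), SEN5 (1.22), AT3G20395 (1.17) and AT2G17880 (1.13). A lower difference was found for APR1 (-2.48), SHM7 (-2.41), OXS3 (-2.34), LSU3 (-2.24), AT1G04770 (-2.16), LSU1 (-1.80), LSU2 (-1.77), MLP423 (-1.60), CIB1 (-1.60), AT1G80440 (-1.09), AT2G20670 (-1.09) and DREB26 (-1.06). For 2 genes with dark levels near 0 in flu1-1 ex1 the call depended on the pseudocount. AT1G47130 had 3.03, which was 1.32 and not called with a pseudocount of 0.1 (adjusted p = 0.507, with 4.04e-05 to 0.507 over all alternatives). MYC2 had -1.66, although its light level was higher in flu1-5 ex1 (40.1 against 20.7 TPM), and -0.20, not called, with a pseudocount of 5 (adjusted p = 0.292, with 5.52e-08 to 0.292 over all alternatives). All values are log2 differences from 3 libraries per group. They are on the log2(TPM + 1) scale, so for low genes they can be larger or smaller than by TPM ratio.

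The pattern most open to follow-up is that 74 of 80 measured members of 5 stress lists (early singlet oxygen, calcium and touch, WRKY, ethylene and ERF, heat shock) had a difference above 0, with a median of 1.05. These lists were pooled because their differences were large, and other stress lists had lower medians: 0.40 for detoxification, 0.32 for salicylic acid and immunity, 0.051 for jasmonate, 0.0076 for hydrogen peroxide, -0.25 for mitochondrial dysfunction and -0.26 for the unfolded protein response, the last 3 not called. Library scaling, a floor effect of low genes and the choice of 1 transcript per gene are argued against, since after quantile normalization the median lay 1.12 above that of all genes, the 66 members with a mean of at least 5 TPM had a median of 1.15 at a pseudocount of 0.1, and the 61 members with a single RefSeq transcript one of 1.07. Of the same 100 splits, 10 gave a median as large in size as the real 1.05, itself included, with -2.10 the highest other, so chance cannot be excluded by this count; the 9 others all keep the light libraries of a line together, and no split that mixes them exceeded 0.91 in size. The flu allele may account for the pattern, as a hypothesis, but neither it nor other differences between the 2 stocks could be tested with 1 stock per allele, and both stay open. A difference between separately grown samples also stays open, since nothing says that the replicates of a group were grown apart.

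The second pattern is a set of 117 genes other than FLU that were at least 2-fold apart between the lines in dark and in light in the same direction, 106 higher and 11 lower in flu1-5 ex1. A segment linked to FLU on chromosome 3 could bring differences of its own, but only 6 of the 117, or 5.13% (exact 95% binomial interval 1.90% to 10.8%), lie within 200 tested genes of FLU on either side. Of all tested genes 2.33% lie there (two-sided Fisher's exact p = 0.0562). Linkage within that window is therefore argued against as the cause of the whole set, and stays open for those 6. They include JAL33, CYP72A11 and NSP4 (chosen after their values were seen). The set overlaps the first pattern, since ZAT12, WRKY40, CML38 and BAP1 are among the 106 higher genes. The share over the whole set says little about the 11 lower genes. Of these, JAL33, NSP4 and AT3G16020 lie in the window, and AT3G01345, AT3G09380, LBD26 and AT3G18535 elsewhere on chromosome 3. The others, MRD1, AT5G26890, AT1G75945 and AT5G26270, lie on other chromosomes. A longer segment was not tested, so linkage also stays open for members further along chromosome 3. Examples are AT3G18320 and AT3G22235, likewise chosen after their values were seen. Whether the remainder follows from the flu allele, from other differences between the stocks or from a difference between separately grown samples was not tested.

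With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In dark, 1 of the 10 splits called as many genes as the real split (3233), which is the real one, and the highest other split called 1. For light against dark in flu1-1 ex1 that number was 1, with 13097 genes in the real split and 0 in the highest other. For flu1-5 ex1 it was 1, with 12297 and 0, and for the lines in light 1, with 6624 and 0.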

How the results depend on the processing

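Alternatives for the lines within dark and within light, and gene list tests without each library, were chosen after seeing the data. Under quantile normalization, each filter, each pseudocount, the replicate block and each left-out library, the counts of called genes in both directions together stayed within 1.5 times the main count in all 5 comparisons. By direction, the genes lower in dark went from 987 to 636 without flu1-1 ex1 dark replicate 1. With 1 library left out the counts ranged from 12429 to 12657 for light in flu1-1 ex1, 11563 to 11724 for flu1-5 ex1, 4686 to 4985 for the difference, 2307 to 2543 between lines in dark and 5668 to 5909 in light. The deposited p-value gave 16105 and 15890 genes for light in the 2 lines, and this alternative was not run for the difference. Stricter thresholds lowered counts by construction. With a change of at least 2-fold they were 3295 in flu1-1 ex1, 2732 in flu1-5 ex1, 504 for the difference, 188 in dark, 668 in light and 2144 for the overlap (main count 10090). At an adjusted p under 0.01 the difference had 3308 genes, dark 1643 and light 4380. With an estimated correlation, 3 of 10 lists kept their calls in flu1-1 ex1 and 0 of 14 in flu1-5 ex1, a test that allows for genes that vary together and has few libraries to estimate it. For light in each line and the difference, a reversal of direction was counted only with a call in the main test or the alternative. There were none among 57 list tests and 201 tests of named genes, left-out libraries aside for lists. Uncalled changes of direction among them were not counted. Within dark and light, 2 uncalled lists changed direction: hydrogen peroxide in dark (by ranks and quantile normalization, adjusted p = 0.882 and 0.897, main 0.727) and chloroplast-encoded in light (by quantile normalization, 0.964, main 0.771). Of those 201 tests, 11 changed side of the threshold under some alternative, 4 of them only with a library left out, and the cause was not tested. For gene lists, quantile normalization ended the calls of 4 of the 57 list tests, ranks added 2 calls in the difference (chloroplast-encoded and tetrapyrrole genes, adjusted p = 0.0364 each) and the block ended 1 (jasmonate in flu1-5 ex1, 0.0523). With 1 library left out, 9 to 10 lists were called in flu1-1 ex1, 13 to 14 in flu1-5 ex1 and 13 to 14 in the difference; the calls lost were PIF and shade in flu1-1 ex1 and jasmonate in flu1-5 ex1, and that gained chloroplast-encoded genes in the difference. In the difference 2 uncalled lists changed direction, chloroplast-encoded genes without flu1-1 ex1 dark replicate 3 (0.789) and the root list of 1 gene without flu1-1 ex1 dark replicate 2 (0.891). Within dark, chloroplast-encoded genes (lower, 0.00425, with 0 of 23 members called) lost their call with an estimated correlation (0.679), with quantile normalization (0.0695) and without flu1-5 ex1 dark replicate 1 (0.0806) and lost it with a change of direction without flu1-1 ex1 dark replicate 3 (0.721). The other lists that changed direction within dark or within light were not called. Replicate numbers did not pair the libraries: of 18 same-number pairs across groups 1 had a correlation of deviations above 0.1 (range -0.062 to 0.153). With the replicate block 13129, 11956, 5060, 2676 and 6052 genes were called in the 5 comparisons, in the order above. Depth is unknown, so its limits cannot be given.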

Other observations

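The tests of the deposited p-values and the sulphur hypothesis itself were chosen after the results were seen. Among the 117 genes at least 2-fold apart between the lines in dark and in light, some were far apart. The following were chosen after their values were seen. AT3G01345 had 153 TPM in dark and 259.5 TPM in light in flu1-1 ex1, against 0.799 and 0.873 TPM in flu1-5 ex1. MRD1 (AT1G53480) had 59.3 and 52.7 TPM against 0.569 and 0.216 TPM. AT3G22235 went the other way, with 0.203 and 0.512 TPM against 15.4 and 13.6 TPM. The log2 differences in dark were -6.42, -5.33 and 3.78. At 0 in all 6 flu1-1 ex1 libraries but with a mean of at least 5 TPM in flu1-5 ex1 were 2 genes, ERF105 and AT2G22880, and 0 genes showed the reverse.

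Some genes of sulphur deficiency stood out among those with a lower difference in flu1-5 ex1 (APR1, SHM7, LSU1, LSU2, LSU3, SDI1 and SDI2, AT1G04770). The hypothesis that the lower difference is shared by this response was tested on 10 further genes of it. They were not among the genes first seen, and were chosen after that pattern was seen but before their values were. Of these, 6 could be tested. Their median difference was -0.78 on the log2 scale, 4 were called lower and 0 higher (camera p = 0.000598, and p = 0.0217 with an estimated correlation). Among them GGCT2;1 (-1.68), APR2 (-1.43) and APR3 (-1.19) had large differences themselves, more than 2-fold. APR2 rose from 49.2 to 334 TPM in flu1-1 ex1 and from 82.5 to 206 TPM in flu1-5 ex1. APR3 rose from 52.1 to 381 TPM and from 101 to 321 TPM. Both had higher mean levels in dark in flu1-5 ex1, so part of their lower difference is a higher starting level. The 7 genes first seen also had higher mean levels in dark there. GGCT2;1, which recycles glutathione, rose from 0.737 to 19.3 TPM and from 0.596 to 4.79 TPM, so its mean level in dark was not higher in flu1-5 ex1. The sulphate transporter genes SULTR2;1 and SULTR4;2 had differences of 0.051 and -0.21, which were not called (adjusted p = 0.644 and 0.871). SULTR4;1 was among the 4 called lower (-0.37), with a log2 change in light of -0.048 in flu1-1 ex1 and -0.42 in flu1-5 ex1, so its lower difference is not a weaker rise. A lower difference may extend beyond the genes first seen, as a hypothesis, but was not found for all of the 6. Nor was a smaller rise in flu1-5 ex1 confined to sulphur genes, being called for 1723 of the 5993 genes that rose in both lines. Levels of sulphur compounds were not measured here.

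The p-values in the authors' deposited table are low even where the fold is close to 1: of genes within 0.05 of 0 on the log2 fold scale, 87.6% of 1142 in flu1-1 ex1 and 84.2% of 1334 in flu1-5 ex1 have a deposited p under 0.05. By limma, on the same libraries, 0% of them have an unadjusted p under 0.05 in either line. That 0% was largely fixed by the standard errors, whose medians were 0.061 in flu1-1 ex1 and 0.064 in flu1-5 ex1. So small a difference could reach such a p by limma for at most 9 of the 1142 and 1 of the 1334. These standard errors argue against a low spread between replicates as what made the small differences significant, for most of these genes. A constant offset between scalings would leave some folds with few low p-values, but over 20 bins of the log2 fold the lowest share was 94.1% in flu1-1 ex1 and 90.2% in flu1-5 ex1 (genes with a mean of at least 5 TPM, 67 or more per bin). Among the near-1 genes the deposited p followed the spread between replicates (Spearman rho 0.917 and 0.936 across genes). A low spread would bring that, but by the standard errors above the spread was too large for most of these genes. What the deposited p-value tests stays open.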
